A study of Mus musculus with 3 samples.

How the data were processed

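The 3 libraries were 10x Chromium 3' single-cell RNA libraries of whole mouse kidney, 1 Eprs+/+ and 2 Eprs+/-. Per the labels' protocols, kidneys were digested with 0.2 mg/ml liberase at 37 °C for 30 min, suspensions were loaded for a target of 10000 cells with version 3.1 chemistry, and libraries were read on a HiSeqX with 28 bp of read 1 and 91 bp of read 2. The labels name the treatment AD without spelling it out, and their wording on the harvest speaks of reperfusion, which the model does not otherwise mention. The authors deposited filtered matrices of raw UMI counts per gene and cell barcode from Cell Ranger 3.1.0, per the submitters' processing notes, which name genome build mm39. The lowest UMI count of any barcode was 500 in each library, and cell calling had been done before deposit. The 32285 Ensembl gene IDs were used as the files pair them with symbols, and 32235 of them were found in GENCODE vM21 (GRCm38), 31502 with the same symbol. Coordinates are from that annotation and were not converted to the submitters' build.

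Cells were kept with at least 200 genes and at most 50% mitochondrial UMIs, which removed 10, 2 and 8 barcodes for genes and 903, 1317 and 1125 for mitochondrial UMIs (order Eprs+/+, Eprs+/- replicate 1, Eprs+/- replicate 2). Median mitochondrial shares over all barcodes were 5.13%, 13.0% and 7.86%, and median UMIs 5747, 6736.5 and 4406.5. Doublets were scored per library with scrublet in scanpy at an expected rate of 8%. Its automatic threshold called 140, 0 and 1 cells, which was taken as a failure, so the 8% of cells with the highest scores were removed instead (959, 1111 and 919), a choice made after those calls were seen. The kept cells were normalized, reduced to 2000 variable genes and 30 principal components, joined by 15 neighbours and clustered over all libraries together by Leiden at resolution 1.0 without batch correction.

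The 37 clusters were named from markers of 18 classes fixed before the data were examined. The scoring rule was set after the clusters were seen: a name needed at least 3 detected markers and no lead of another class among the top 10 genes, and names are given as X-like. Cluster 4 stayed unnamed and held 3.56%, 3.15% and 9.22% of kept cells. Its leading genes were Calb1 and S100g of the distal nephron. The fixed markers of injured and of other proximal tubule cells were merged to name 1 class after the clusters were seen, so injured cells were not counted apart. The erythroid name also needed a marker other than hemoglobin. No cluster took the name mast cell. The proximal tubule-like clusters 1, 12 and 22 had none of the fixed markers among their top 10 genes. Clusters 1 and 22 were led by stress and detoxification genes such as Cbr3 and Cyp2a5, and cluster 12 by Mlxipl and unnamed transcripts. When each library was clustered alone, 93.5%, 93.9% and 69.7% of its cells took the same name. Doublet scores and clusters shifted with the last digits of floating-point arithmetic, which differ between processors, so the numeric libraries were pinned to 1 instruction set. The results were computed anew after that pinning, which was added when a rerun on unpinned libraries had given other clusters. Clustering from another seed, an alternative added then, gave 34 clusters, 1 of them unnamed, and left 99.1%, 98.6% and 98.4% of cells in the same class.

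Cells are not replicates, so UMIs were summed per library and class. Classes with at least 50 kept cells in every library were compared, 11 in all. Stromal-like cells met that minimum by 1 cell. In the unpinned run they had missed it and had been added at a minimum of 30, a choice made after the cells were counted, so their comparison was seen before. Sums were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment over the genes of a class, threshold 0.05, with 1 residual degree of freedom. In T and NK cell-like cells edgeR estimated infinite prior degrees of freedom, so the test there treated the spread as known, which makes calls easier. The per-library log2 ratios used a prior count of 0.5, and folds against 0 UMIs used a floor of 3 counts. Shares of classes were tested with the same model on cell counts. The 32 gene lists, also fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a class. Many of them measure cell makeup as well as state, and the mitochondrial, hemoglobin and proximal tubule free RNA lists were included to measure RNA quality and RNA from other cells.

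Named genes followed a rule fixed before the data were examined: Eprs, up to 10 genes in each direction with at least 20 CPM and the same sign in both Eprs+/- libraries, ranked by fold among genes that passed and otherwise filled by unadjusted p, and up to 4 members of each list by p. Gene models without a name, immunoglobulin and T cell receptor segments were left out of the ranking. Havcr1, Lcn2, Spp1, Gm43305, Wdfy1, and the genes named in B and plasma cell-like cells, were named outside the rule after their values were seen.

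The alternatives fixed beforehand were RLE size factors in edgeR, DESeq2 1.42.0, no filter on low counts, a mitochondrial ceiling of 30%, doublets kept, Leiden at resolution 0.5, each library clustered alone, TMM across classes for shares, camera with an estimated correlation, 10000 random lists matched on mean expression, and leaving out each Eprs+/- library. Median log2 fold changes of all genes of a class lay between -0.03 and 0.03 under TMM, RLE and DESeq2 scaling.

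The fit was tested on simulated counts with the means and library sizes of the real samples and 50 genes changed at each of 4 fold sizes. At the dispersion of the class, 2-, 4-, 8- and 16-fold changes were recovered for 0%, 22%, 80% and 94% of genes in the sum over all cells (18446 genes, 41 false calls), for 12%, 86%, 100% and 100% in proximal tubule-like cells (15159 genes, 61 false calls) and for 14%, 70%, 98% and 100% in T and NK cell-like cells (10186 genes, 5 false calls). In the first 2 of these the false calls exceeded the nominal 5% of calls. With the dispersion set to 0.01, 96%, 100% and 76% of 2-fold changes and 100% of larger ones were recovered.

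All 3 libraries carried Y-linked transcripts (Ddx3y at 44.6, 50.8 and 52.0 CPM) and next to no Xist, as the male label requires. Figures were drawn with matplotlib 3.10.9, and clustering used scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1 and igraph 0.11.9 under Python 3.11.15. The kept cells held 123889812, 121410958 and 105560049 UMIs. At this depth the exact Poisson interval of Eprs in the sum over all cells ran from 105 to 108 CPM before TMM scaling in Eprs+/+, so counting error was small beside the spread between libraries. Intervals and floors cover counting error only.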

Results

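Single-cell RNA profiles were made from whole kidneys of male C57BL/6 mice aged 8 weeks in a toxin-induced model of tubulointerstitial nephritis (TIN), an inflammation of the kidney tubules and the tissue between them. The 3 libraries carried the day label D14. One came from an Eprs+/+ kidney and 2 from Eprs+/- kidneys, called replicate 1 and replicate 2 here. Eprs encodes the glutamyl-prolyl-tRNA synthetase, which charges tRNA with glutamate and proline, and the series title names an inhibitor of the prolyl activity. None of the 3 libraries was labelled with that inhibitor, so the labels allow a single contrast, Eprs+/- against Eprs+/+, which asks how an injured kidney with 1 disrupted Eprs allele differs from one with both alleles intact. The files held 12897, 15210 and 12622 cell barcodes with 140322106, 141383326 and 119229971 UMIs (unique molecules), in the order Eprs+/+, Eprs+/- replicate 1 and Eprs+/- replicate 2. Wherever 3 values stand together they follow that order, and levels are in CPM, the UMIs of a gene per 1e6 UMIs after normalization. After quality filters 11025, 12780 and 10570 cells remained. The labels do not say whether the libraries came from separate animals, so no p-value speaks for more than these 3 libraries. The p-values of edgeR rest on the spread between the 2 Eprs+/- libraries, pooled wholly or in part over genes. The lone Eprs+/+ library was assumed to vary like them. Camera, the test of gene lists, compared listed genes with the other genes at its preset correlation, so those p-values do not measure the spread between libraries. With an estimated correlation camera rested on 1 residual degree of freedom. That version could hardly call any list, so its adjusted p-values below neither back nor refute a list.

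Eprs itself was lower in both Eprs+/- libraries. Summed over all cells it stood at 98.5, 59.3 and 60.8 CPM, a mean of 60.1 ± 1.05 CPM (SD, n = 2) in Eprs+/-, which placed the Eprs+/- libraries at 60.2% and 61.7% of the Eprs+/+ level. Both Eprs+/- libraries lay below Eprs+/+ in each of the 11 compared cell classes, between 20.6% and 80.1% of its level, and in 12 of the 13 classes with a value. The exception was the neutrophil-like class, where Eprs+/- replicate 2 stood at 104.7% of Eprs+/+ on 27 Eprs UMIs. In T and NK cell-like cells Eprs fell (204, 41.9 and 90.2 CPM, log2 fold change -1.50, SE 0.36, adjusted p = 0.00698 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), on 13 Eprs UMIs in replicate 1. It passed with neither RLE size factors nor DESeq2, and without replicate 1 the log2 ratio there was -1.17. In the sum over all cells the log2 fold change was -0.71 (SE 0.28) and did not pass the test (adjusted p = 0.938, edgeR's quasi-likelihood test). Eprs (ENSMUSG00000026615) is annotated on the plus strand of chromosome 1 at 185363044 to 185428360 in GENCODE vM21 (GRCm38). Which part of the gene the allele lacks is not stated in the labels, so 3' end counts check the genotype only as far as the allele lowers the whole transcript.

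**Figure D1:**
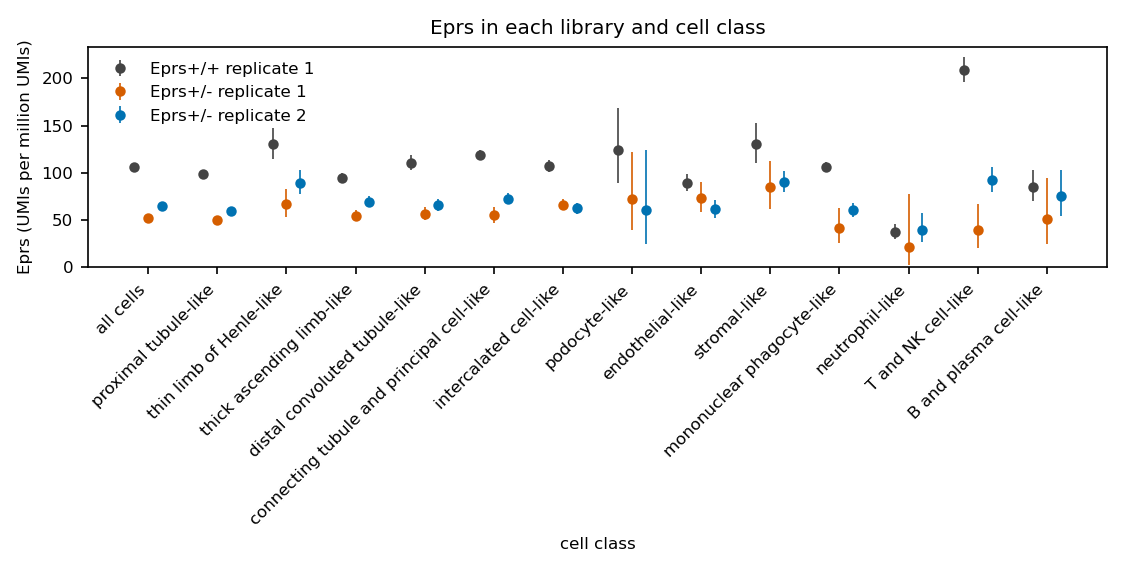
Eprs in each cell class (x axis), as CPM before TMM scaling (y axis), with 1 point per library and exact Poisson 95% intervals for counting error only. Both Eprs+/- points lie below the Eprs+/+ point in every class drawn except neutrophil-like cells, and the Eprs+/+ T and NK cell-like cells reach the highest value drawn.

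The makeup of the 3 digested kidneys differed widely, and the 2 Eprs+/- kidneys lay on the same side of Eprs+/+ for the most abundant classes. Proximal tubule-like cells made up 25.2%, 74.9% and 42.9% of kept cells, a mean of 58.9 ± 22.6% (SD, n = 2) in Eprs+/-. Immune-like cells were scarcer in both Eprs+/- libraries. Mononuclear phagocyte-like cells made up 17.7%, 1.12% and 6.39%, T and NK cell-like cells 9.93%, 0.657% and 5.48%, neutrophil-like cells 8.60%, 0.2504% and 2.89% and B and plasma cell-like cells 3.44%, 0.579% and 1.97%. Connecting tubule and principal cell-like cells (5.41%, 2.11% and 2.78%), podocyte-like cells (0.934%, 0.297% and 0.322%), urothelium-like cells (0.299%, 0.0626% and 0.0568%) and erythroid-like cells (1.88%, 0.642% and 0.189%) also had smaller shares in both. Shares are parts of a whole, so the 74.9% of proximal tubule-like cells in replicate 1 lowers the shares of all other classes there. Stromal-like cells (1.23%, 0.399% and 2.54%) and endothelial-like cells (5.61%, 2.15% and 7.15%) lay below Eprs+/+ in replicate 1 and above it in replicate 2. Thick ascending limb-like cells made up 4.63%, 3.32% and 3.14%, distal convoluted tubule-like cells 6.92%, 6.26% and 6.63%, intercalated cell-like cells 3.56%, 3.29% and 5.73% and thin limb of Henle-like cells 0.898%, 0.728% and 1.32%. By the quasi-likelihood test on cell counts none of the 16 classes changed: 0 passed, 0 had an unadjusted p under 0.05, and the smallest Benjamini-Hochberg adjusted p in edgeR was 0.598. The test had 1 residual degree of freedom, and an exact permutation of 1 library against 2 cannot go below p = 0.333. Exact binomial intervals, which cover counting error only, were narrow, for mononuclear phagocyte-like cells 17.7% (17.0 to 18.4), 1.12% (0.944 to 1.32) and 6.39% (5.93 to 6.87).

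**Figure D2:**
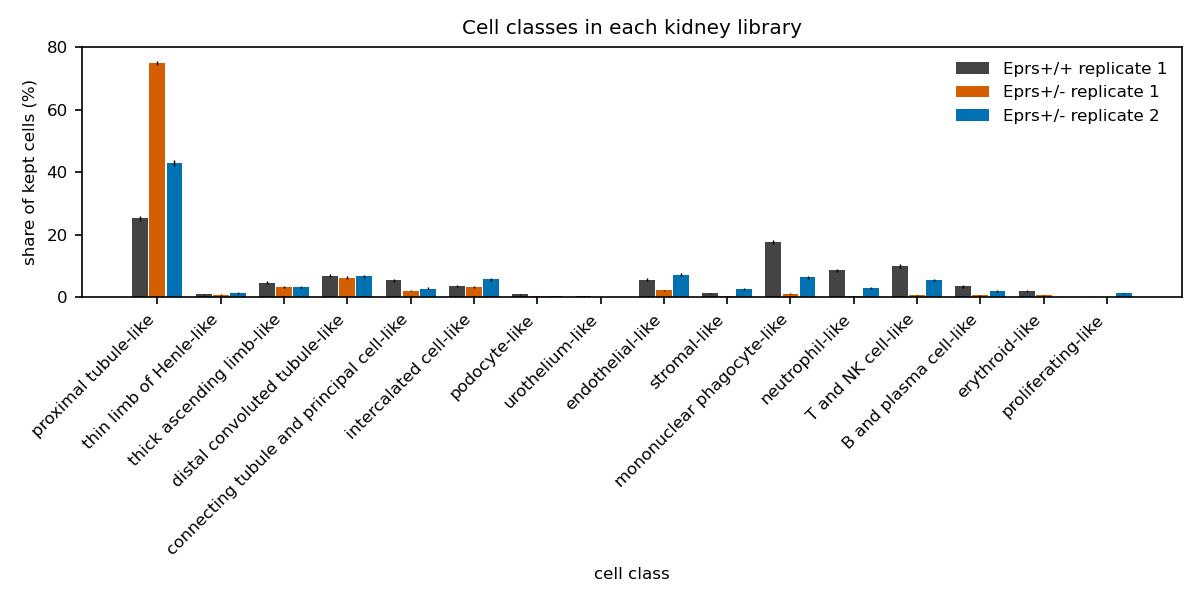
Share of kept cells in each class (y axis, percent) for each library, with exact binomial 95% intervals for counting error only. Proximal tubule-like cells make up 25.2%, 74.9% and 42.9%, and mononuclear phagocyte-like cells 17.7%, 1.12% and 6.39%.

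Within the sum over all cells, transcripts of the proximal tubule and of fatty acid oxidation were higher in both Eprs+/- libraries, and inflammatory transcripts were lower. Gldc of the glycine cleavage system stood at 9.89, 46.2 and 39.9 CPM and the growth factor gene Mdk (midkine) at 22.0, 75.5 and 73.1 CPM. The interferon-induced Ifi27l2a stood at 182, 19.6 and 34.5 CPM, the monocyte marker Ly6c2 at 46.4, 10.2 and 13.7 CPM, the endothelial VEGF receptor gene Kdr at 56.7, 19.8 and 20.1 CPM, and the immediate early genes Nr4a2 and Nr4a1 at 42.9, 6.74 and 12.5 CPM and 139, 58.5 and 68.9 CPM. None of these passed. Of 18922 genes tested, edgeR's quasi-likelihood test called 0 at a Benjamini-Hochberg adjusted p under 0.05, with 231 at an unadjusted p under 0.05, and DESeq2 called 11, 2 higher and 9 lower, most of them immunoglobulin and keratin genes.

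Of the 32 gene lists fixed in advance, 18 were called in the sum over all cells with camera's preset correlation, 6 higher and 12 lower. Fatty acid oxidation was higher in both libraries for 27 of 28 members (median log2 fold change 0.98, for example Acaa1b at 117, 460.5 and 294 CPM). Proximal tubule transport was higher for 31 of 35 (median 1.22), and nuclear genes of oxidative phosphorylation for 38 of 40 (median 0.59). Lower in both were 28 of 29 cytokine and NF-kappaB genes (median -1.71, Ccl3 at 72.8, 5.57 and 19.7 CPM, Nfkbia at 389, 98.3 and 196 CPM), 8 of 8 MHC class II genes (median -2.32), 26 of 31 interferon response genes (median -1.22), 26 of 32 tubule injury genes (median -1.26, Icam1 at 77.5, 21.0 and 45.2 CPM) and 15 of 19 genes of the TGF-beta list (median -0.76, Tgfb1 at 61.1, 5.27 and 27.3 CPM). The amino acid response list of ATF4 targets was lower for 20 of 29 members (median -0.69, Slc7a1 at 20.7, 6.01 and 11.9 CPM), and proline metabolism was higher for 8 of 12 (median 0.84, Prodh, which starts proline breakdown, at 32.8, 117 and 73.7 CPM). The medians leaned on replicate 1. In replicate 1 and replicate 2 they were 1.26 and 0.71 for fatty acid oxidation, 1.72 and 0.67 for transport, 0.82 and 0.30 for oxidative phosphorylation, -3.61 and -1.01 for cytokines, -4.35 and -1.49 for MHC class II, -1.91 and -0.76 for interferon, -3.16 and -0.64 for injury, -1.32 and -0.31 for TGF-beta, -1.02 and -0.29 for the amino acid response and 1.23 and 0.37 for proline metabolism. Camera's Benjamini-Hochberg adjusted p ranged from 7.5e-17 for cytokines to 0.0209 for proline metabolism, and was 0.756 for each of these 10 lists with an estimated correlation. The other cytosolic tRNA synthetases (median -0.06, adjusted p = 0.831), the unfolded protein response (0.08, 0.636) and the collagens (0.32, 0.488, with medians of -0.92 in replicate 1 and 0.77 in replicate 2) were not called by camera. Adjusted over the list alone, 0 members passed edgeR's quasi-likelihood test in any list of this sum. The measured shares of cell classes moved with these lists, and mitochondrial transcripts took 8.64%, 16.6% and 10.9% of UMIs (list higher, adjusted p = 5.5e-06 by camera, adjusted p = 0.756 with an estimated correlation).

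Proximal tubule-like cells, the cells that reclaim most of the filtered solutes, carried fewer transcripts of the tubule injury list in Eprs+/- replicate 1 than in either other library. Of 32 tested members, 25 were lower in both Eprs+/- libraries, with a median log2 ratio -3.64 in Eprs+/- replicate 1 and -0.32 in Eprs+/- replicate 2. The cytokine genes Il34 and Ccl2 and the adhesion gene Icam1 stood at 48.1, 2.47 and 16.8 CPM, 7.72, 0.497 and 2.91 CPM and 45.7, 18.2 and 34.2 CPM. Of the best known injury markers, chosen after their values were seen, Havcr1 (kidney injury molecule 1) stood at 189, 1.17 and 50.9 CPM, Lcn2 at 99.0, 0.414 and 93.4 CPM and Spp1 (osteopontin) at 11413, 659 and 10374 CPM. Cytokine and NF-kappaB genes were lower in both for 26 of 26 members (medians -3.55 and -0.75). Immune-like cells together made up 39.7%, 2.61% and 16.7% of kept cells, and free RNA from them was not measured. Less of that free RNA cannot be told from lower cytokine expression in proximal tubule-like cells. The injury list (adjusted p = 4.8e-14) and the cytokine list (4.2e-18) were called lower by camera with its preset correlation. With an estimated correlation the adjusted p was 0.830 for both.

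**Figure D3:**
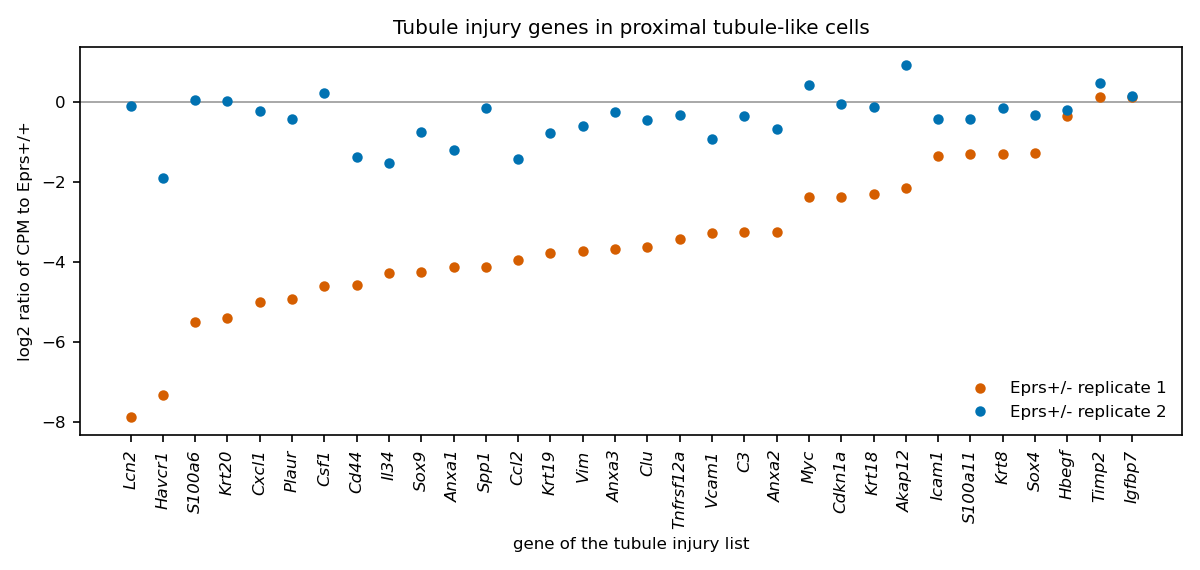
Log2 ratio of CPM to the Eprs+/+ library (y axis) for each gene of the tubule injury list (x axis) in proximal tubule-like cells, with 1 point per Eprs+/- library. The median is -3.64 in replicate 1 and -0.32 in replicate 2.

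Genes of energy metabolism differed by smaller amounts than injury genes in proximal tubule-like cells. Fatty acid oxidation was higher in both for 20 of 28 members (median 0.35, per library 0.32 and 0.28), among them Acaa2, the last thiolase of mitochondrial beta-oxidation, at 133, 316 and 288 CPM, while Crot, which acts on fatty acids in peroxisomes, stood at 443, 229 and 275 CPM. Oxidative phosphorylation was higher for 31 of 40 (median 0.26, per library 0.41 and 0.12), with Ndufv1 of complex I at 179, 250.2 and 225 CPM. The amino acid response list was lower for 19 of 29 members (medians -1.28 and -0.17), including Psat1 of serine synthesis at 32.3, 14.7 and 18.7 CPM and Sesn2 at 39.6, 27.7 and 28.7 CPM. Camera's adjusted p values were 1.6e-04, 8.3e-05 and 7.6e-07 for the 3 lists. Each had an adjusted p of 0.830 with an estimated correlation. Hemoglobin transcripts, which these cells do not make, were lower for 4 of 4 members at 0.0605%, 0.0269% and 0.0387% of UMIs (adjusted p = 1.9e-04 by camera, adjusted p = 0.830 with an estimated correlation).

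By rank, the genes higher in both were Spns3 (21.4, 50.8 and 52.8 CPM), the cyclin gene Ccnd1 (51.7, 146 and 182 CPM), Acot3 (12.7, 37.5 and 29.8 CPM), the kynurenine pathway gene Kynu (17.7, 35.2 and 33.6 CPM) and the corticoid-induced kinase gene Sgk1 (65.7, 158 and 198 CPM). Those lower in both were Pigr (57.8, 23.9 and 23.8 CPM), which carries IgA across epithelia, Ttr (547, 129 and 177 CPM), the thyroid hormone carrier transthyretin, and Wsb1 (62.5, 31.1 and 30.8 CPM). None passed. Of 15535 genes, edgeR's quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, 156 had an unadjusted p under 0.05, and DESeq2 called 7, among them Ccnd1 higher and Ttr lower. Adjusted over the list alone, 0 members of the injury, cytokine, fatty acid, oxidative phosphorylation, amino acid response and hemoglobin lists passed. The proximal tubule-like cells of replicate 1 came largely from other clusters than those of the other libraries: clusters 13, 25, 26, 32 and 36 held 96.6% of them, against 4.79% in Eprs+/+ and 1.92% in replicate 2, whose cells lay mostly in clusters 1, 7, 10, 12, 21 and 22.

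Thick ascending limb-like cells, which dilute the urine, showed the same direction for injury genes. Of 32 tested members of the tubule injury list, 23 were lower in both Eprs+/- libraries, with a median log2 ratio -2.81 in Eprs+/- replicate 1 and -0.29 in Eprs+/- replicate 2. Sox9, a transcription factor gene of regenerating tubules, stood at 50.02, 21.1 and 22.8 CPM and Icam1 at 42.9, 4.94 and 22.4 CPM. The interferon response list had 16 of 25 members lower (medians -0.87 and -0.34), with Isg15 at 59.8, 17.2 and 26.7 CPM and Cxcl10 at 186, 29.7 and 87.4 CPM. Rasl11a (119, 28.0 and 49.8 CPM), Phlda1 (44.7, 8.06 and 17.1 CPM) and Sgk1 (79.0, 15.01 and 35.3 CPM) were lower in both, and Fkbp5, a glucocorticoid-induced gene, was higher (25.3, 56.0 and 52.1 CPM). Proximal tubule transcripts, foreign to this segment, were also higher in both, with 31 of 34 transport genes (median 1.66, per library 2.10 and 0.78) and Miox at 8.37, 208 and 34.0 CPM. Camera called the injury (adjusted p = 5.8e-16), interferon (2.3e-04) and transport (2.8e-24) lists with its preset correlation. Each had an adjusted p of 0.695 with an estimated correlation. By edgeR's quasi-likelihood test 0 of 12935 genes passed after adjustment, 127 had an unadjusted p under 0.05, DESeq2 called 1 (Miox, higher), and 0 members of these lists passed when adjusted over the list alone. Signs of RNA quality moved with replicate 1 too: mitochondrial transcripts took 10.5%, 23.8% and 10.5% of UMIs, median UMIs per cell were 21368, 12553.5 and 18829, and ribosomal protein genes were lower for 36 of 36 in replicate 1 (median -0.74).

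Stromal-like cells, the fibroblasts, pericytes and muscle cells between the tubules, numbered 136, 51 and 268. Collagen genes as a list stood on opposite sides of Eprs+/+ in the Eprs+/- libraries, with a median log2 ratio -2.08 in Eprs+/- replicate 1 and 0.56 in Eprs+/- replicate 2. Col3a1, a fibrillar collagen of scars, stood at 1343, 43.8 and 894 CPM, Col6a2 at 46.5, 31.5 and 111 CPM and the matrix protease inhibitor gene Timp1 at 2355, 3.50 and 974 CPM. The collagen list was not called (adjusted p = 0.117 by camera), its median at 0.01, its mean at 0.00462 and the test leaning lower. The other matrix list (median -0.31, adjusted p = 6.3e-04, adjusted p = 0.891 with an estimated correlation) had per-library medians of -2.08 and 0.32. Contractile genes were lower in both for 9 of 11 members (median -0.61, per library -0.46 and -0.59), with Acta2, the smooth muscle actin of myofibroblasts, at 1696, 1156 and 803 CPM and Myl9 at 689, 533 and 297 CPM. Interferon-induced genes were higher in both for 15 of 30 (median 0.42, per library 0.70 and 0.13), with Ifit3 at 14.04, 70.1 and 47.6 CPM and Gbp2 at 21.1, 45.6 and 54.5 CPM. Both lists were called by camera (adjusted p = 4.5e-04 and 4.4e-06), with an adjusted p of 0.891 for each with an estimated correlation. The integrin gene Itga8 (50.001, 5.26 and 13.6 CPM) and the endothelin receptor gene Ednrb (329.8, 87.6 and 128 CPM) were lower in both. Some transcripts of other cells were higher in both, such as the endothelial Gpihbp1 (9.65, 38.5 and 75.2 CPM) and the tubule transporter gene Slc12a1 (7.02, 226 and 33.7 CPM). The proximal tubule list for free RNA took 0.445%, 1.28% and 0.329% of UMIs and mitochondrial transcripts 4.59%, 7.92% and 3.59%. EdgeR's quasi-likelihood test called 0 of 10763 genes after adjustment, 111 had an unadjusted p under 0.05, DESeq2 called 0, and 0 members of these 4 lists passed when adjusted over the list alone. Cluster 34, led by Dcn and Mgp, held 29, 6 and 173 of these cells, and cluster 8, led by Ren1 and Rgs5, held 107, 45 and 95.

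In endothelial-like cells 2 genes were called higher, and both mark lymphatic endothelium. No cluster was set apart as lymphatic, and the cells with these transcripts were not counted. The presence of lymphatic cells in a library therefore cannot be told from higher expression within cells. Ccl21a (ENSMUSG00000094686), a chemokine that draws dendritic cells and T cells to lymphatic vessels, had 0 UMIs in Eprs+/+ and 109 and 205 CPM in Eprs+/-, at least 230.5-fold higher against a floor of 3 counts in the Eprs+/+ library. Mmrn1 (multimerin 1) had 0 UMIs in Eprs+/+ and 40.8 and 44.3 CPM in Eprs+/-, at least 62.5-fold higher. The adjusted p was 0.0404 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11780 genes, of which 622 had an unadjusted p under 0.05. DESeq2 called 11 genes, 1 of them shared. Ccl21a has near-identical copies in the mouse genome, so its counts are uncertain. No gene passed with doublets kept, with a mitochondrial ceiling of 30% or with each library clustered alone. The class mixed cluster 3, led by Plvap, with 238, 143 and 573 cells, cluster 17, led by Plat and Ehd3, with 178, 61 and 52, and cluster 20, led by Cldn5 and Sox17, with 203, 71 and 131. Genes lower in both included Pdgfrb (57.4, 11.1 and 9.41 CPM), Hopx (77.4, 20.4 and 14.1 CPM), Gata3 (50.4, 15.3 and 8.62 CPM), the Notch target Hey1 (39.7, 13.6 and 13.3 CPM) and Cxcl10 (62.2, 7.65 and 19.99 CPM), none past the test. Pdgfrb is a fixed stromal marker and Gata3 a fixed connecting tubule and principal cell marker. For these 2 genes a different mix of cells or free RNA cannot be told from lower endothelial expression. Cytokine genes were lower for 17 of 21 members (median -1.002, per library -1.74 and -0.54, adjusted p = 6.4e-09 by camera, adjusted p = 0.666 with an estimated correlation), with 0 adjusted over the list alone. Free RNA of immune-like cells was not measured here either. Proximal tubule transport genes, foreign to these cells, were higher for 28 of 30 members (median 1.91, per library 2.43 and 1.09, adjusted p = 9.2e-24, adjusted p = 0.666 with an estimated correlation), and 14 passed edgeR's test adjusted over the list alone. Transcripts of the proximal tubule list for free RNA took 0.185%, 1.25% and 0.377% of their UMIs and mitochondrial transcripts 3.29%, 6.80% and 4.60%.

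Mononuclear phagocyte-like cells, the macrophages, monocytes and dendritic cells of the kidney, carried fewer proliferation transcripts in Eprs+/-. Cell cycle genes were lower in both libraries for 19 of 20 members, with a median log2 ratio -2.99 in Eprs+/- replicate 1 and -0.64 in Eprs+/- replicate 2, Stmn1 at 115, 23.9 and 72.1 CPM and Ube2c at 31.9, 3.67 and 15.9 CPM. The class held 17771404, 529483 and 4681003 UMIs, so levels of a few CPM in replicate 1 rest on few UMIs. A different mix of cells, described below, was not separated from lower expression of the cell cycle list. Camera called the list lower (adjusted p = 3.7e-18), with an adjusted p of 0.881 with an estimated correlation and 0 members passing when adjusted over the list alone. The chemokine gene Cxcl1 stood at 4.97, 14.7 and 55.2 CPM, Ccl22 at 63.3, 0 and 16.4 CPM, the neutrophil transcript S100a9 at 127, 0 and 24.7 CPM, the heme-degrading enzyme gene Hmox1 at 130.2, 36.7 and 65.7 CPM and the lipoprotein lipase gene Lpl at 272, 141 and 129 CPM, none past the test. Proximal tubule transport genes were again higher, for 26 of 32 members (median 1.64, per library 2.47 and 0.81, adjusted p = 1.6e-21, adjusted p = 0.881 with an estimated correlation, 9 adjusted over the list alone). The reported targets of the EPRS-containing GAIT complex, a translational silencer in myeloid cells, were called lower (median -0.22, adjusted p = 0.00280, adjusted p = 0.881 with an estimated correlation, 1 adjusted over the list alone), with per-library medians of -1.19 and 0.14. One gene rose of 11793, the unnamed transcript Gm43305 (log2 fold change 4.47, SE 0.58, adjusted p = 0.00877 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in both libraries), named here after its value was seen. Its level was 1.66, 36.7 and 37.1 CPM on 29, 20 and 170 UMIs. In connecting tubule and principal cell-like cells Gm43305 stood at 35.2, 721 and 730 CPM, so free RNA from those cells stays open. DESeq2 also called 1, the same gene, edgeR with RLE size factors or with doublets kept called 0, and 284 genes had an unadjusted p under 0.05. Replicate 1 gave 143 of these cells, against 1952 in Eprs+/+ and 675 in replicate 2, and the class mixed different cells: cluster 18, led by Cd209a and H2-Ab1, held 28.3%, 2.80% and 13.9% of it and cluster 16, led by C1qa, 38.3%, 55.9% and 58.2%. Mitochondrial transcripts took 2.60%, 6.47% and 3.56% of its UMIs.

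In T and NK cell-like cells Il17a, the gene of the cytokine interleukin-17A, fell, as did several genes known from gamma-delta T cells, a group not tested as a list, and Gzma and Ccl4, genes active in cytotoxic cells, rose. Il17a stood at 422, 0 and 111 CPM (log2 fold change -2.62, SE 0.34, adjusted p = 1.9e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cd163l1, Ccr6, Blk and Actn2 fell with it, with 61.7, 0 and 19.9 CPM for Cd163l1, 48.0, 9.68 and 13.7 CPM for Ccr6, 67.9, 12.9 and 23.0 CPM for Blk and 88.6, 16.1 and 27.4 CPM for Actn2. Cluster 5, led by Il17a and Trdc, held 27.3%, 2.38% and 13.1% of the class. Without that cluster Il17a and Ccr6 were still called lower, Cd163l1 and Actn2 were not, and Blk was no longer tested. Of cell cycle genes, 19 of 20 were lower in both libraries (median -0.98, per library -0.85 and -0.98, adjusted p = 2.0e-17 by camera, adjusted p = 0.793 with an estimated correlation), and Ube2c (95.5, 19.4 and 31.4 CPM), Cenpf (41.8, 6.45 and 9.73 CPM) and Top2a (114, 35.5 and 48.6 CPM) fell, with 11 members passing when adjusted over the list alone. The granzyme gene Gzma (729, 3329 and 903 CPM) and the chemokine gene Ccl4 (313, 1135 and 613 CPM) rose, and cluster 6, led by Gzma, Ccl5 and Prf1, held 12.8%, 32.1% and 13.1% of the class. The fixed list of T cell activation and effector genes was called lower (median -0.45, adjusted p = 0.0231 by camera, adjusted p = 0.793 with an estimated correlation), with per-library medians of -1.44 and -0.09 and 10 members passing edgeR's quasi-likelihood test adjusted over the list alone.

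Many other calls in T and NK cell-like cells were of genes those cells do not make. Miox (34.6, 481 and 71.6 CPM), G6pc (5.17, 87.1 and 12.8 CPM), Nat8 (6.57, 74.2 and 17.7 CPM) and Akr1c21 (55.1, 435 and 73.8 CPM), all proximal tubule transcripts, rose. The hemoglobin genes fell, 4 of 4, with Hba-a1 at 348, 25.8 and 91.1 CPM and Hbb-bs at 859.5, 74.2 and 310.4 CPM. The proximal tubule list for free RNA took 0.270%, 1.21% and 0.292% of UMIs and hemoglobin 0.161%, 0.0124% and 0.0504%, and camera called them higher (adjusted p = 1.6e-09) and lower (4.0e-16), with an adjusted p of 0.793 for each with an estimated correlation. Adjusted over the list alone, 8 and 4 members passed edgeR's quasi-likelihood test. In all, 63 of 10616 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 29 higher and 34 lower, and 381 had an unadjusted p under 0.05. Some genes called higher had opposite signs in the Eprs+/- libraries. Kap (853, 7374 and 188 CPM) and Acsm2 (40.8, 332 and 35.4 CPM) were higher in replicate 1 only, and Mgp (10.9, 9.68 and 62.3 CPM) in replicate 2 only. With RLE size factors 12 passed, 3 higher and 9 lower, and with DESeq2, or with doublets kept in edgeR, 0 did. Of the genes named in this class only Il17a, Miox, Hba-a1 and Hbb-bs also passed with RLE size factors. Replicate 1 held 84 of these cells, against 1095 in Eprs+/+ and 579 in replicate 2, and the values lean on it. Without it the log2 ratio was -1.93 for Il17a, -1.79 for Ccr6, -2.08 for Cenpf, 0.31 for Gzma, 0.97 for Ccl4 and 1.04 for Miox, with no test possible.

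The other classes were summarised as counts. EdgeR's quasi-likelihood test with adjustment called 0 of 10897 genes in thin limb of Henle-like cells (142 at an unadjusted p under 0.05, 0 by DESeq2), 0 of 12807 in distal convoluted tubule-like cells (206, and 1 by DESeq2), 0 of 13678 in connecting tubule and principal cell-like cells (87, and 6 by DESeq2) and 0 of 13293 in intercalated cell-like cells (427, and 59 by DESeq2). It called 50 of 6423 genes in B and plasma cell-like cells, 7 higher and 43 lower, with 284 at an unadjusted p under 0.05, 6 by DESeq2, and 77 with RLE size factors, of which 16 were higher and 61 lower.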

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

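Clustering from another seed, T and NK cell-like cells without 1 cluster, and Eprs by DESeq2 were tests chosen after the data were seen. No paired analysis was possible because the groups share only replicate number 1. The cause of the changes below was not tested, except that leaving out the filter adds genes of few counts. Eprs in the sum over all cells kept its direction under RLE size factors and DESeq2, with log2 ratios of -0.73 to -0.70 when each Eprs+/- library was left out.

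No cell class changed in share with TMM across classes, a mitochondrial ceiling of 30%, doublets kept, Leiden at resolution 0.5, each library clustered alone or another seed. Counts of changed genes moved widely. With DESeq2 they were 11 in the sum over all cells, 7 in proximal tubule-like, 1 in thick ascending limb-like, 1 in distal convoluted tubule-like, 6 in connecting tubule and principal cell-like, 59 in intercalated cell-like, 11 in endothelial-like, 0 in T and NK cell-like and 6 in B and plasma cell-like cells. Without the low-count filter they were 89 in thin limb of Henle-like, 76 in thick ascending limb-like, 141 in distal convoluted tubule-like, 50 in connecting tubule and principal cell-like, 120 in intercalated cell-like, 287 in endothelial-like, 47 in mononuclear phagocyte-like and 19 in stromal-like cells. With RLE size factors they were 0 in mononuclear phagocyte-like, 12 in T and NK cell-like and 77 in B and plasma cell-like cells. With a mitochondrial ceiling of 30% they were 0 in endothelial-like cells. With doublets kept they were 0 in endothelial-like, 0 in mononuclear phagocyte-like, 0 in T and NK cell-like and 83 in B and plasma cell-like cells. With each library clustered alone they were 0 in endothelial-like and 101 in B and plasma cell-like cells. At Leiden resolution 0.5 and from another seed every class kept its count, with 63 in T and NK cell-like and 50 in B and plasma cell-like cells.

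With an estimated correlation camera called 0 lists in the sum over all cells and 0 in each of the 11 classes, against 10 to 19 with the preset correlation. Random matched lists placed 12 to 22 lists per class past the threshold.

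With all 3 libraries, other settings changed the sign of the share of 4 classes, none of them past the test. With doublets kept the log2 ratio was 0.01 (0.0116) for thick ascending limb-like cells. With each library clustered alone it was 0.53 for thick ascending limb-like, 0.06 (0.0585) for distal convoluted tubule-like and -0.13 for stromal-like cells. With TMM across classes it was 0.62 for thick ascending limb-like, 1.02 for distal convoluted tubule-like and 0.61 for endothelial-like cells. Leaving out a library, with no test possible, also moved shares. Without replicate 2 the log2 ratio changed sign in stromal-like (0.25 to -1.62), thin limb of Henle-like (0.19 to -0.30), intercalated cell-like (0.34 to -0.11) and proliferating-like cells (1.98 to -0.54). It went to -5.08 in neutrophil-like, -3.91 in T and NK cell-like, -3.98 in mononuclear phagocyte-like, -2.56 in B and plasma cell-like and -1.38 in endothelial-like cells. Without replicate 1 it went from -0.27 to 0.35 in endothelial-like and from 0.25 to 1.04 in stromal-like cells, and shrank to -0.86 in T and NK cell-like, -0.80 in B and plasma cell-like, -1.47 in mononuclear phagocyte-like, -1.57 in neutrophil-like and 0.77 in proximal tubule-like cells.

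No gene named in the text changed direction under another tool or without the filter. In T and NK cell-like cells no named gene passed with DESeq2, and with RLE size factors all but Il17a, Miox, Hba-a1 and Hbb-bs were lost. In proximal tubule-like cells the log2 ratio without replicate 2 was -7.32 for Havcr1, -7.87 for Lcn2 and -4.11 for Spp1, so the size of the injury result rests on replicate 1. One residual degree of freedom and classes with 51 to 143 cells in replicate 1 limit what these data can resolve.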

Other observations

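The tests in this part chosen only after the result was seen were those on the wrong label, the yield of cell classes, tubule injury, DNA beside the Eprs allele and free RNA, with the class used for free RNA and the genes kept without the Il17a-richest cluster set again after a first result. The choice of the genes in B and plasma cell-like cells, and of Gm43305 and Wdfy1, was also made after their values were seen.

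In B and plasma cell-like cells several genes of antibody-secreting cells, chosen after their values were seen and not tested as a list, fell in both Eprs+/- libraries. Iglc1, an immunoglobulin light chain gene, fell from 41178 CPM in Eprs+/+ to 365 and 275 CPM (log2 fold change -7.01, adjusted p = 8.3e-40 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and its near-identical relatives make its counts uncertain. Mzb1 (936, 281 and 247 CPM) and Xbp1 (396, 138 and 44.4 CPM), which serve antibody secretion, and Slpi (1029, 0 and 1.78 CPM), a protease inhibitor gene among those leading the neutrophil-like cluster, fell as well. The hemoglobin genes fell in these cells too, with Hba-a1 at 963, 21.2 and 124 CPM. Of these genes DESeq2 also called Iglc1, Mzb1 and Slpi, but not Xbp1 or Hba-a1. This class was cluster 23 alone, with 379, 74 and 208 cells. Antibody-secreting cells were not counted apart within it, so fewer such cells cannot be told from lower expression. The prior degrees of freedom of edgeR were 58.8 here, so its p-values rest mostly on spread pooled over genes. Proliferating-like cells numbered 19, 15 and 132, and their share did not pass the test (log2 fold change 1.98, adjusted p = 0.655 by edgeR's quasi-likelihood test).

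Eprs+/- replicate 1 stood apart from the other libraries. With that library set against the other 2, the same model called 1044 genes in proximal tubule-like cells and 2943 in thick ascending limb-like cells, against 0 and 0 for the genotype split and 0 and 0 with replicate 2 alone, which points to a structure of the samples in these classes, and 3 splits are too few for a share under 0.05. With replicate 1 alone it called 0 in the sum over all cells, 0 in endothelial-like cells (2 for the genotype split) and 9 in B and plasma cell-like cells (50 for the genotype split). A wrong genotype label is argued against by its Eprs, at a median log2 ratio of -0.82 to Eprs+/+ over the 11 compared classes. A different yield of cell classes at digestion alone was examined with 2 lists within proximal tubule-like cells. The transport list, seen first, lay at 0.37, between the bounds. The tubule injury list lay -2.96 from the nearer of the other libraries relative to all genes. It was chosen after its values were seen and is part of the pattern, so it does not decide this cause. A loss of injured cells within the class stays open too. Less tubule injury in that kidney stays open: the list was lower in proximal tubule, thick ascending limb and connecting tubule and principal cell-like cells against each other library, with medians of -2.57 or lower, but these values restate the pattern and do not test it, and toxin dose, animal and genotype were not tested either.

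Gm43305 and Wdfy1 differed between Eprs+/+ and both Eprs+/- libraries across classes, Gm43305 higher in 10 of 11 classes and Wdfy1 lower in 11 of 11 (median log2 ratios -1.87 and -1.38). DNA of a donor strain carried beside the Eprs allele is argued against by distance, since Wdfy1 lies 105.66 Mb from Eprs on chromosome 1 and Gm43305 on chromosome 14 (GENCODE vM21, GRCm38), although separate segments elsewhere stay open. Gm43305 was highest in connecting tubule and principal cell-like cells (35.2, 721 and 730.1 CPM), with a log2 ratio of at least 4.36 in both libraries. That argues against free RNA of another class as the source in those cells only. In other classes free RNA from those cells stays open for Gm43305, as in mononuclear phagocyte-like cells (1.66, 36.7 and 37.1 CPM). For Wdfy1 free RNA stays undecided, because the answer depends on the class, which was set again after a first result. In endothelial-like cells, where Wdfy1 was highest in Eprs+/+ (71.7, 11.1 and 26.7 CPM), the log2 ratios were -2.65 and -1.42 (1.42 or more in size), on 13 UMIs in replicate 1. In proximal tubule-like cells, where it was highest on average, they were -0.75 and -1.10, the first of them between the bounds. A background mixed from C57BL/6J and C57BL/6N could also separate the genotypes, but Nnt, the gene that parts these substrains, gave a median absolute log2 ratio of 0.550 on levels of 0.681 to 5.26 CPM in Eprs+/+, between the bounds. In proximal tubule-like cells Nnt had 160, 269 and 191 UMIs and log2 ratios of -0.35 and -0.21, no shift past 1, but no other class held more than 36 Nnt UMIs in a library, so the background cannot be told apart.

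The calls in T and NK cell-like cells may have several sources. For the genes called higher, free RNA of proximal tubule cells is a candidate source, since 79.3% of them (23 of 29) had more CPM in proximal tubule-like than in T and NK cell-like cells of both Eprs+/- libraries, Gzma and Ccl4 not among them. Kap and Acsm2, counted among the 23, lay below Eprs+/+ in replicate 2. For the genes called lower, a smaller share of Il17a-expressing cells within the class was tested by leaving out cluster 5, the richest in Il17a, which held 27.3%, 2.38% and 13.1% of the class. Their median log2 fold change went from -1.98 to -1.55 over the same 34 genes, so that 78.4% of it remained (95% bootstrap interval over genes 70.3 to 96.1). That median also covers hemoglobin and cell cycle genes. Of the 30 that still passed the count filter 17 were still called lower. Il17a and Ccr6 kept their call, Cd163l1 and Actn2 lost it, and Blk was no longer tested. Without the cluster, Eprs+/+ levels were 80.1 CPM for Il17a, 9.32 CPM for Cd163l1 and 18.1 CPM for Actn2. These values do not decide between fewer such cells and lower expression. Without the cluster 24 genes were called higher and 21 lower. The genotype split called 63 genes in this class and the split with Eprs+/- replicate 1 alone 336, and 3 splits are too few for a share under 0.05.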
